A study of Drosophila melanogaster with 10 samples.

How the data were processed

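RNA from Drosophila SL2 cells, an established male cell line derived from embryos, was hybridised to 10 Affymetrix expression arrays, 1 array per sample. The deposited table holds 1 log2 expression value per probe set and array, which per the submitters' processing notes were made with GCRMA, a method that corrects the background, normalises across arrays and summarises probes. Its version and any other step are not given in the sources used here. The log2 scale of the deposited values was checked on the table, whose lowest value was 2.22, and no further normalisation was applied for the results given first.

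Samples were grouped by the source name in the labels. The groups were GST dsRNA (3 arrays), the MBD-R2 constructs M1 and M2 (3 arrays each) and cells without dsRNA (1 array). The title of the third M2 array names M3, while its source name and description give M2, and it was grouped as M2. Per the series' design text the replicates are biological. The number of arrays limits the precision of every value, and the lone array without dsRNA was assumed to vary like the other groups.

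Of 18952 probe sets, 183 are controls and were left out of the tests. Among the rest, 13646 carried 1 gene in the platform annotation, 402 carried several and 4721 were unnamed here. Symbols, chromosome arms, gene lengths and neighbours were taken from the RefSeq annotation of Release 6, matched by Entrez identifier for 13543 probe sets. Coordinates were not used otherwise. Overlaps of named genes with other annotated genes are not reported here. A gene was represented by its probe set with the highest mean over the 10 arrays, among probe sets that name 1 gene. Probe sets with a mean log2 value of at least 4 were tested, which left 7298 probe sets and 5906 genes. The transcript targeted by the constructs, MBD-R2, was not analysed here, so its depletion was not checked and knockdown below names the treatment.

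Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the 4 group means of all 10 arrays. Tests were two-sided with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The comparisons were the mean of M1 and M2 against GST, each construct against GST, M2 against M1, and the array without dsRNA against GST. Gene lists, 43 in number, were tested with limma's camera, at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 42 lists with tested members. In 2 list entries the symbol and the gene number named different genes, and the symbol was used. A further 2 entries matched no gene. The X chromosome was compared with chromosomes 2 and 3 as the difference of mean log2 values per array, 1 probe set per gene, by exact two-sided permutation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

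Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Named genes were the members of the NSL and MSL lists, the 12 largest rises and 12 largest falls of the combined comparison among genes with a symbol other than a bare CG or CR number that also passed with each construct, and up to 4 called members of each other list by smallest adjusted p, or the 1 with the smallest p where none was called. For the M2 against M1 and no-dsRNA comparisons up to 5 called genes each way were to be named. A gene named beyond this rule is said to be chosen after its values were seen.

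Replicate numbers were checked as pairs by correlating each array's deviations from its group mean. Over 9 pairs of arrays with the same number r lay between 0.34 and 0.93. A fit with the replicate number as a block was run, treating the numbers as pairs. The deviations also separated the arrays of the dsRNA groups into 2 sets, replicates 1 and 2 against replicate 3. The array without dsRNA, alone in its group, has no deviation and was placed with replicate 3 by its control probe sets. Over 6 pairs with different numbers in the same set r was 0.55 to 0.75, and over 12 pairs across the sets it was -0.89 to -0.54. In replicates 1 and 2 GST arrays correlated less with knockdown arrays of their own number (0.34 to 0.49) than the other (0.55 to 0.67). M1 and M2 arrays correlated more within numbers (0.79 and 0.83) than across them (0.70 and 0.75). Apart from the split into 2 sets, the correlations therefore do not establish the numbers as pairs. This split is called the array set below. A fit with the array set as a block, and one on replicates 1 and 2 alone, were added after seeing the data, as was spike-in centring with GST replicate 2 left out.

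The other alternatives were no filter or a filter at a mean of 6, quantile normalisation of the deposited values, centring on the hybridisation spike-in controls or on the median, eBayes with trend and robust options, array weights, a fit of the compared groups alone, pooled controls, stricter thresholds, 1 probe set per gene, and leaving out each array. On simulated data with 200 changed probe sets of 7298, the combined comparison recovered 54% of those changed by 1 log2 unit and 87% of those changed by 2, with 8 false calls. With a simulated difference between array sets these shares were 39% and 81% with 0 false calls, against 92% and 99% with 20 false calls when the set was a block. Camera at the preset correlation called the shifted list in 20 of 20 simulated data sets and 1 of 800 unchanged lists. The simulated genes varied independently, so this does not show how that setting performs when the genes of a list are correlated.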

Results

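Messenger RNA levels were measured in SL2 cells 7 days after exposure to 10 µg of double-stranded RNA. Cells received dsRNA against GST, used here as the control, or 1 of a pair of constructs (M1, M2) against MBD-R2, a subunit of the NSL chromatin complex that contains the histone acetyltransferase MOF. Each of these groups had 3 arrays, and 1 more array came from cells without dsRNA. Between 50.6% and 53.2% of the probe sets of an array lay within 0.1 log2 units of the lowest value in the table.

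Knockdown of MBD-R2 was compared with GST dsRNA to ask which transcripts depend on the protein. The largest fall was that of Gr61a, a gustatory receptor gene, from a log2 level of 7.09 ± 0.11 (SD, n = 3) in GST arrays to 2.51 ± 0.07 with M1 and 2.51 ± 0.06 with M2. Its log2 fold change was -4.58 ± 0.11 (SE, 6 arrays against 3, adjusted p = 9.1e-07). Falls were also seen for Uxt, which encodes a prefoldin-like protein (-4.23 ± 0.24), Sdhaf3, a succinate dehydrogenase assembly factor (-4.14 ± 0.36), and Surf1, an assembly factor of cytochrome c oxidase (-3.56 ± 0.18). Mis12, a kinetochore protein gene (-3.63 ± 0.18), Nse1 of the Smc5/6 complex (-3.82 ± 0.18) and nxf2, an RNA export factor homologue (-3.83 ± 0.24), fell as well. The remaining falls were those of the mitochondrial tyrosyl-tRNA synthetase gene TyrRS-m (-3.67 ± 0.18), Ir76a (-4.31 ± 0.25), GstE13 (-3.89 ± 0.41), f-cup (-3.69 ± 0.19) and sgll (-3.69 ± 0.38). In 7 of these 12 genes (Gr61a, Ir76a, Uxt, Sdhaf3, nxf2, Nse1 and TyrRS-m) a knockdown group ended within 1 log2 unit of the lowest table value, which limits the fall that could be measured.

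The largest rise was that of a glutathione S-transferase gene, GstD5, from 4.65 ± 1.07 (SD, n = 3) in GST arrays to 9.80 ± 0.90 with M1 and 9.33 ± 1.54 with M2, a log2 fold change of 4.92 ± 0.74 (SE, adjusted p = 0.0018). GstD2 rose by 3.43 ± 0.68, the UDP-glycosyltransferase gene Ugt302K1 by 3.73 ± 0.50, and the cytochrome P450 genes Cyp9b1 and Cyp6d2 by 4.77 ± 0.77 and 3.37 ± 0.76. Without GST replicate 2, Cyp6d2 had an adjusted p of 0.0513. The pigmentation genes y and e rose by 4.11 ± 0.25 and 3.84 ± 0.65, Pu, which encodes GTP cyclohydrolase, by 3.47 ± 0.24, and the cuticular protein gene Cpr49Ac by 3.49 ± 0.68. Obp49a, an odorant-binding protein gene, Apoltp, an apolipoprotein gene, and Cyt-b5-r rose by 4.18 ± 0.90, 4.16 ± 0.82 and 3.71 ± 0.55. Cyp9b1, Obp49a and Cyp6d2 started within 1 log2 unit of the lowest table value. All 12 largest falls and all 12 largest rises kept their direction both within replicates 1 and 2 and within replicate 3. They also passed the test with spike-in centring. Since they were chosen for large changes on these same arrays, this is not an independent check.

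In limma's test 1843 of 7298 probe sets changed, 573 higher and 1270 lower (68.9% lower), and 1164 of them by over 2-fold (335 higher, 829 lower). The split depended on the scaling of the arrays, with 57.8% of 1922 calls lower after quantile normalisation and 45.6% of 252 calls lower after spike-in centring, which moved the median log2 fold change of all tested probe sets from -0.03 to 0.21. The direction of that shift rests on GST replicate 2, whose spike-in median was 12.77 against 10.33 and 10.45 in the other GST arrays. Without this array spike-in centring gave 91.1% of 1185 calls lower and a median of -0.62, in a fit added after seeing the data. With the replicate number as a block 3189 probe sets passed (1313 higher, 1876 lower), with the array set as a block 3541 (1482 higher, 2059 lower), and in replicates 1 and 2 alone 2838 (1205 higher, 1633 lower). Replicate 3 holds 1 GST array and gave no test of its own, but 2614 (92.1%) of those 2838 had the same sign there, 1585 of 1633 falls and 1029 of 1205 rises. In a test added after seeing the data the effect differed between the array sets at 723 probe sets in limma, with 408 larger in replicate 3, 44 smaller and 271 of opposite sign.

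Mitochondrial ribosomal protein genes formed the list with the smallest p in camera at the preset correlation. Of 71 measured members 52 fell and 0 rose (0 higher and 58 lower when adjusted over the list alone), with a median log2 fold change of -1.15. Among those that fell were mRpL2 (-3.50 ± 0.22), mRpS28 (-2.16 ± 0.18), mRpL48 (-1.55 ± 0.13) and mRpS18B (-1.47 ± 0.12). Camera gave an adjusted p of 2.6e-14 at the preset correlation and adjusted p = 0.55 with an estimated correlation. The list median was -1.04 within replicates 1 and 2 and -1.28 in replicate 3, with 61 members lower and 1 higher when the array set was a block (adjusted p = 2.6e-14, and adjusted p = 0.47 with an estimated correlation). After spike-in centring the median was -0.91, or -1.12 relative to all probe sets as with the deposited scaling, and 1 member passed as lower. In the cytosolic list 0 of 29 ribosomal protein genes passed limma's test, with a median of -0.07 that became 0.17 after spike-in centring (-0.61 without GST replicate 2) and 0.01 after median centring. Their mean level of 15.42 in GST arrays lay near the highest array values of 16.12 to 16.50, which limits the change that could be measured. RpLP0, the member with the smallest p, had a log2 fold change of -0.17 ± 0.12 (adjusted p = 0.355).

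Of 25 S phase genes, which act in DNA replication, 13 fell and 0 rose (1 higher and 17 lower when adjusted over the list alone), with a median of -0.92. Those that fell included 3 members of the GINS complex, which acts in the replicative helicase. Psf2 fell by 3.02 ± 0.27, Psf1 by 1.93 ± 0.25 and Sld5 by 1.59 ± 0.21, while Orc5 of the origin recognition complex fell by 1.85 ± 0.19. The list's adjusted p was 0.00027, and adjusted p = 0.72 with an estimated correlation. Its median was -0.70 in replicates 1 and 2 and -1.24 in replicate 3 (adjusted p = 0.0011 with the array set as a block, and adjusted p = 0.47 with an estimated correlation), -0.61 without GST replicate 3 and -0.53 with the filter at a mean of 6. Of 52 genes of general transcription and RNA polymerase II 22 fell and 0 rose (0 higher and 24 lower when adjusted over the list alone), with a median of -0.38. MED27 and MED11, subunits of Mediator, fell by 2.09 ± 0.18 and 1.70 ± 0.17, the TFIIH helicase gene Xpd by 2.02 ± 0.23 and Taf6 of TFIID by 0.94 ± 0.11. This list's adjusted p was 0.0009, and adjusted p = 0.22 with an estimated correlation. Its median was -0.39 in replicates 1 and 2 and -0.40 in replicate 3 (adjusted p = 0.0017 with the array set as a block, and adjusted p = 0.24 with an estimated correlation). After spike-in centring the medians of both lists stayed below 0, at -0.68 and -0.14, with 1 S phase gene and 0 transcription genes passing in limma.

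Of 24 oxidative stress and xenobiotic genes 8 rose and 1 fell (10 higher and 1 lower when adjusted over the list alone), with a median of 0.95. Besides GstD5, GstD9 rose by 1.83 ± 0.15 and the catalase gene Cat by 1.43 ± 0.22, while GstE13 was the member that fell. The list's adjusted p was 0.00027, and adjusted p = 0.24 with an estimated correlation. With the array set as a block 16 members were higher and 2 lower (adjusted p = 1.9e-05, and adjusted p = 0.24 with an estimated correlation), with medians of 0.90 in replicates 1 and 2 and 1.09 in replicate 3, and without the level filter the median was 0.44. Of 9 glycolytic genes 6 rose and 0 fell (6 higher and 0 lower when adjusted over the list alone), with a median of 0.55. Pfk, which encodes phosphofructokinase, rose by 1.08 ± 0.21 and Tpi by 0.92 ± 0.20, and without GST replicate 1 Tpi had an adjusted p of 0.0558. The other 2 members named by the rule, Eno (0.55 ± 0.15) and Gapdh1 (0.41 ± 0.12), lost their call in 4 and 8 of the leave-one-out fits. The adjusted p of this list was 0.0014, and adjusted p = 0.24 with an estimated correlation. Its medians were 0.39 in replicates 1 and 2 and 0.91 in replicate 3 (adjusted p = 0.0035 with the array set as a block, and adjusted p = 0.47 with an estimated correlation). Under spike-in centring both medians stayed above 0, at 1.19 and 0.79 (0.24 and 0.01 without GST replicate 2), and 3 oxidative stress genes but 0 glycolytic genes passed as higher in limma.

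**Figure D1:**
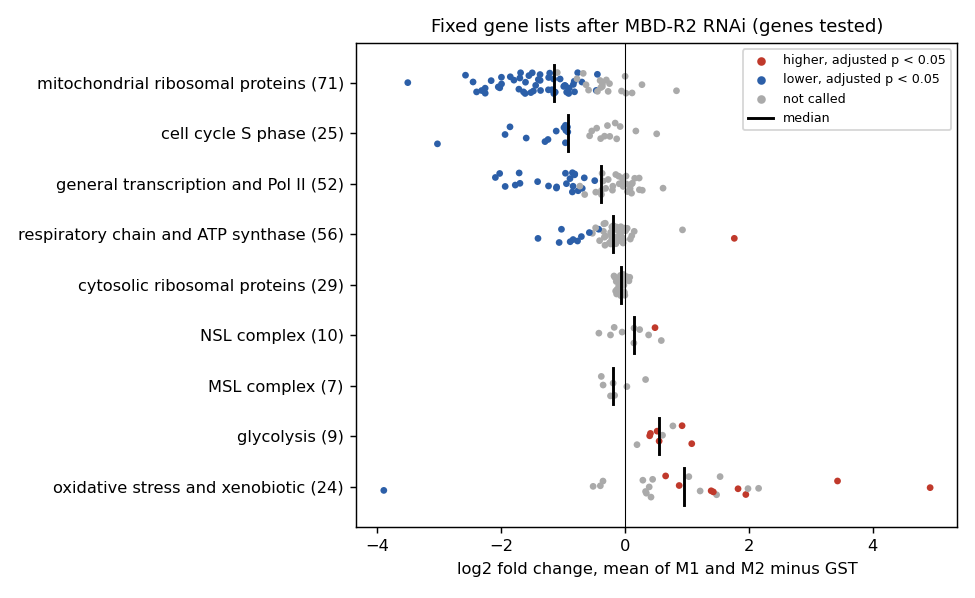
Log2 fold change of each tested gene (mean of M1 and M2 minus GST, horizontal axis) in 9 gene lists, with coloured points for genes past the adjusted threshold and a black line at each list's median. Mitochondrial ribosomal protein genes lie around a median of -1.15 and cytosolic ones around -0.07, the latter becoming 0.17 after spike-in centring; the medians of the MSL and respiratory chain lists likewise turn positive after spike-in centring, and all 3 are negative there without GST replicate 2.

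Gene lists for the complexes that share MOF, NSL and MSL, were examined because the series concerns dosage compensation. This process raises expression of the single male X. Members below are members of a list, which need not be core subunits. Of 10 measured NSL members 1 passed limma's test, nsl1, at 0.49 ± 0.13 (adjusted p = 0.0276), and 0 passed when adjusted over the list alone. Its call was lost without GST replicate 1 (adjusted p = 0.096), GST replicate 3 (0.0725), M1 replicate 2 (0.0556), M1 replicate 3 (0.0518) or M2 replicate 1 (0.0507). The other members did not pass, with mof at -0.23 ± 0.23, Rcd5 at 0.59 ± 0.25, Chro at -0.42 ± 0.24, Nup153 at 0.38 ± 0.27, Rcd1 at 0.24 ± 0.19, pzg at -0.17 ± 0.13, Mgtor at 0.15 ± 0.12, wds at 0.15 ± 0.24 and dgt1 at -0.04 ± 0.13. With the replicate number as a block Rcd5 had an adjusted p of 0.0026, and with the array set as a block 3 members were higher, nsl1, Rcd5 (adjusted p = 0.00088) and Nup153 (0.0377). Among 7 MSL members 0 passed in limma, including the gene for the male-specific subunit, msl-2 (-0.35 ± 0.39), the helicase gene mle (0.33 ± 0.37), msl-3 (-0.38 ± 0.36), msl-1 (0.03 ± 0.40), Clamp (-0.19 ± 0.18) and JIL-1 (-0.16 ± 0.47). The MSL median was -0.19, which became 0.06 after quantile normalisation and 0.05 after spike-in centring (-0.91 without GST replicate 2), and the NSL median was 0.15. The camera adjusted p was 0.44 for the NSL and 0.94 for the MSL list.

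The constructs were compared with each other because a pair of dsRNAs against 1 transcript shares the intended target and differs in sequence. The largest changes were nearly equal, as for Gr61a (-4.58 ± 0.13 with M1, -4.58 ± 0.13 with M2), mRpL2 (-3.43 ± 0.25 and -3.57 ± 0.25) and y (4.15 ± 0.29 and 4.06 ± 0.29). M1 changed 1487 probe sets (414 higher, 1073 lower) and M2 1375 (388 higher, 987 lower). Of these, 1281 changed alike with both (346 higher, 935 lower) and 0 in opposite directions. Independent lists of these sizes would share 22 rises and 145 falls, and simulated unchanged groups against the same GST arrays shared at most 1 call in 100 simulations. Across probe sets, which are not independent replicates, the fold changes correlated at r = 0.984 against a simulated 0.50, with a covariance of 0.867 against 0.080 (0.794 within replicates 1 and 2). The simulation draws arrays independently, whereas deviations of same-numbered M1 and M2 arrays correlated at 0.79 to 0.93, so it may understate what unchanged groups share. The GST arrays are too few to split, so part of the excess over independent lists may come from the shared controls.

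In the direct test of M2 against M1, limma called 0 of 7298 probe sets, with 19 at an unadjusted p under 0.05. The difference lay within ±0.5 log2 units for 98.3% of probe sets. In this fit, which has no block, the median half-width of its confidence interval at limma's default level was 0.612. Smaller differences between the constructs were therefore mostly not detectable in it with 3 arrays each. Fits with the replicate number or the array set as a block also called 0 in limma, with 80 and 116 at an unadjusted p under 0.05. With the replicate number as a block M1 changed 2729, M2 2647 and both alike 2402 probe sets. With the array set as a block these counts were 3078, 3017 and 2702, and in replicates 1 and 2 alone 2531, 2291 and 2085. After spike-in centring they were 166, 125 and 103.

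**Figure D2:**
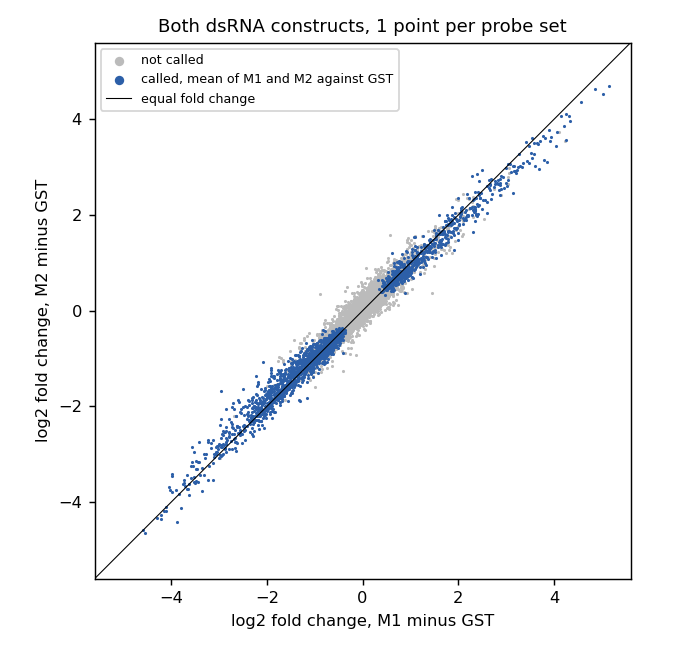
Log2 fold change against GST with construct M2 (vertical axis) plotted against construct M1 (horizontal axis), 1 point per tested probe set. The points follow a line, with r = 0.984 across 7298 probe sets, against 0.50 for simulated unchanged groups that share the GST arrays.

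Cells without dsRNA were set against GST dsRNA to give the background of dsRNA exposure. Of genes that fell after MBD-R2 knockdown, Uxt had a log2 level of 7.32 in this array against 7.21 ± 0.46 (SD, n = 3) with GST, and mRpL2 8.29 against 8.18 ± 0.19. Among genes that rose, y had 6.06 against 6.26 ± 0.38, whereas GstD5 had 6.08 against 4.65 ± 1.07, Apoltp 7.30 against 5.30 ± 1.84 and e 4.76 against 6.33 ± 1.63. GstD5, Apoltp and e lay within 0.31 log2 units of GST replicate 3, so their distance from the GST mean follows the spread of the GST arrays. Over all knockdown falls of more than 2-fold the median difference of this array from GST was 0.11, and over all such rises -0.04. Limma called 0 probe sets, with 68 at an unadjusted p under 0.05. With 1 array, which shares its array set with 1 of the 3 GST arrays, this does not show an absence of effects of dsRNA. Without GST replicate 3 it called 1, and without the filter on the mean level 242. This array resembled GST replicate 3 most closely, differing from it by over 2-fold at 16 probe sets, whereas GST replicates 1 and 2 differed from each other at 256.

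Genes of the X chromosome fell less often than genes of chromosomes 2 and 3. Of 995 tested X-linked genes 136 were lower (13.7%), against 1035 of 4854 on chromosomes 2 and 3 (21.3%; odds ratio 0.584, confidence interval 0.478 to 0.710 at R's default level, Fisher's exact test, two-sided, p = 1.4e-08, adjusted over 8 tests 1.1e-07). With the array set as a block the shares were 25.2% and 32.9% (odds ratio 0.689, Fisher's exact p = 1.9e-06). Rises did not differ, with 6.53% on the X and 7.56% on chromosomes 2 and 3 (Fisher's exact p = 0.287). On chromosome 4, the small autosome, 0 of 42 genes fell in limma's test and 4 rose, with 0 lower also when the array set was a block (Fisher's exact p = 7.4e-05 and 1.1e-07). Fisher's test counts genes as independent although all were measured on the same arrays. Its p values therefore do not reflect the variation between arrays. The X-linked genes that changed included y, with the rise given above, and the respiratory chain genes ND-B18 and ND-ASHI, which fell by 1.06 ± 0.19 and 0.83 ± 0.15.

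The mean level of X-linked genes relative to chromosomes 2 and 3 was -0.13 ± 0.03 (SD, n = 3) in GST arrays, -0.03 ± 0.02 with M1, -0.03 ± 0.02 with M2, and -0.11 in the array without dsRNA. The difference between knockdown and GST arrays was 0.10 log2 units (exact permutation over 84 splits, two-sided, p = 0.0119, adjusted over the X and chromosome 4 0.0238), with each of 6 knockdown arrays above each of 3 GST arrays. Permuted within replicate numbers the exact p was 0.037, the smallest that 27 choices allow, and for each construct alone it was 0.1, the smallest for 3 against 3. The difference was 0.13 within replicates 1 and 2 (exact p = 0.0667, the smallest of 15 splits) and 0.05 in replicate 3, which has 1 GST array. As a gene set in camera the X did not pass (p = 0.189 at the preset correlation, p = 0.529 with an estimated one). For chromosome 4 the difference was 0.44 (exact permutation, two-sided, p = 0.0714 over 84 splits). Paired by replicate number the exact p was 0.037, the smallest of 27 choices, and each knockdown array lay above the GST array of its number. The difference was 0.43 in replicates 1 and 2 and 0.45 in replicate 3.

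**Figure D3:**
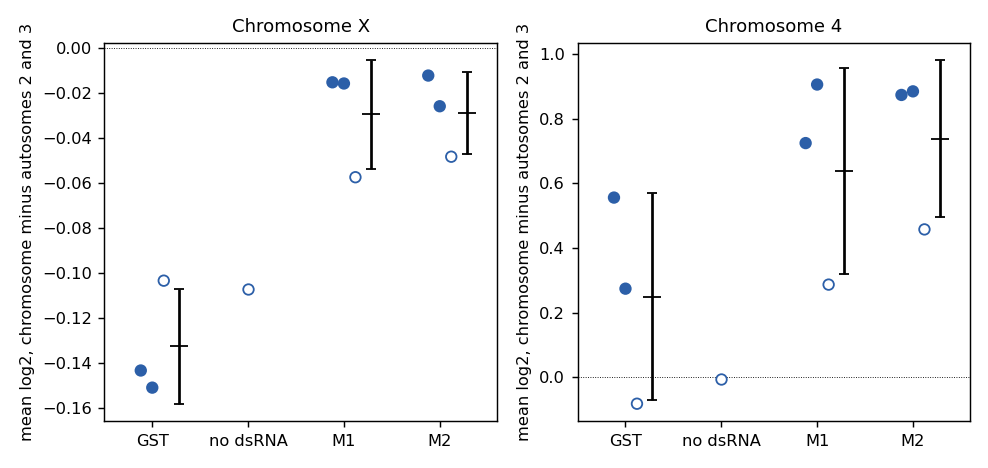
Mean log2 level of X-linked and chromosome 4 genes minus that of genes on chromosomes 2 and 3, 1 point per array, with bars for the mean ± SD of 3 arrays; filled circles are replicates 1 and 2, open circles replicate 3 and the array without dsRNA. For the X, the 3 GST arrays lie between -0.15 and -0.10 and the 6 knockdown arrays between -0.06 and -0.01.

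Falls were least frequent among probe sets of high level. In quartiles of the mean over all arrays, which a fall itself lowers, the share that fell was 30.7%, 23.7%, 12% and 3.18% from the lowest to the highest, while the share that rose was 8.60%, 7.79%, 8% and 7.01%. Ranked by the level in GST arrays alone, falls made up 18.8%, 26.6%, 17.9% and 6.19%, and rises 13.6%, 7.29%, 5.59% and 4.93%.

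The arrays differed in ways that the groups do not explain. Poly-A spike-in controls averaged 2.40 log2 units higher in replicate 3 of each dsRNA group and the array without dsRNA than in the other 6. The 5′ probe sets of actin, GAPDH and eIF-4a were lower relative to the 3′ probe sets by -1.63. Exact permutation, two-sided, gave p = 0.00476 of 210 splits for both. The array set was itself seen in the control probe sets, so this p is no independent test of it. The controls added at hybridisation differed by -0.58 (exact p = 0.219). With group as a block 3687 probe sets differed between replicate 3 and replicates 1 and 2 in limma (1802 higher, 1885 lower). Each dsRNA group holds arrays of both kinds in the same numbers. The median SD within groups was 0.339 over 3 arrays and 0.157 over replicates 1 and 2.

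**Figure D4:**
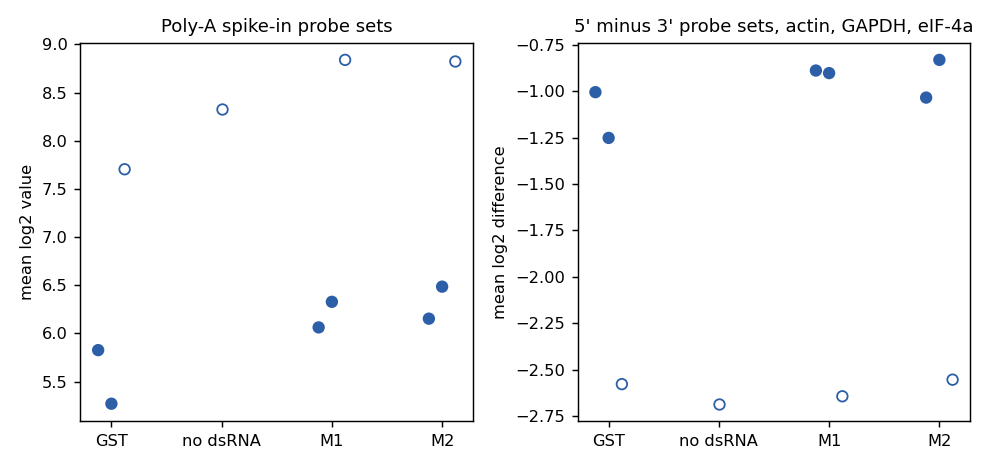
Mean log2 level of control probe sets per array, by group, with filled circles for replicates 1 and 2 and open circles for replicate 3 and the array without dsRNA. The poly-A controls lie between 5.27 and 6.49 in the filled arrays and between 7.70 and 8.84 in the open ones.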

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

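The 18S ribosomal RNA control probe sets, 3 in number, reached 14.92 in M1 replicate 3, the highest knockdown array, against 7.23 to 10.60 in the control arrays. They were marked because they lie outside the comparisons tested here and a knockdown array exceeded every control by more than the range of the controls. The knockdown arrays ranged from 3.75 to 14.92, and averaged 9.24 ± 3.98 (SD, n = 6) against 9.15 ± 1.73 (n = 3) with GST (exact permutation, two-sided, p = 0.952). The difference of the single array was not tested.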

How the results depend on the processing

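Single genes were refitted under the scalings, the trend and robust options, both blocks, pooled controls and leaving out each array. The 12 largest rises and 12 largest falls, chosen for their size on these same arrays, kept their sign in all of these. Of 105 called named genes 68 stayed called in all but spike-in centring, in which 33 did. Of the alternatives for single genes 1728 left the result the same, 270 weakened it, 18 strengthened it and 0 reversed a call. Changed probe sets in limma for M1 and M2 combined, M1, M2, and alike with both numbered 1843, 1487, 1375 and 1281. Spike-in centring gave 252 (45.6% falls), 166, 125 and 103, and, added after seeing the data, 1185 (91.1% falls), 1285, 605 and 585 with GST replicate 2 left out as well. Quantile normalisation gave 57.8% falls. An adjusted p under 0.01 gave 1061, 801, 709 and 668, and at least 2-fold 1164 combined. Array weights gave 2341 with M1, 2555 with M2 and 2130 alike. The replicate block gave 3189 (58.8% falls), 2729, 2647 and 2402, and among named genes it added only Rcd5, Dcp-1 and Hsc70-5. Beyond the counts, these genes and the chromosome 4 shift it ended or added no call of a named gene, list or shift. The array set (batch) block, added after seeing the data, gave 3541 (58.1% falls), 3078, 3017 and 2702, and replicates 1 and 2 alone 2838 (57.5% falls), 2531, 2291 and 2085. Leaving out each array gave 1400 to 1784 combined, 1059 to 1632 with M1, 960 to 1444 with M2 and 937 to 1138 alike. M2 against M1 stayed at 0 under every setting. For no dsRNA the count was 242 without a filter on the mean level, and 0 to 1 on leaving out each array, with 1 without GST replicate 3 (adjusted p = 0.0147). Of the gene lists 5 passed, 14 without a filter, 0 with an estimated correlation, and 0 with the array set block and an estimated correlation. The X minus autosome shift of 0.10 was 0.05 without a filter on the mean level and 0.13 in replicates 1 and 2 alone. Where these counts moved, the cause was not tested. The replicate block, the fit of compared groups alone and pooled controls were not run for the array without dsRNA, and neither were 10 alternatives for the target gene.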

Other observations

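The split of the tRNA synthetases below was chosen only after the result was seen. Of 9 synthetase genes with a mitochondrial symbol 5 were lower and 0 higher in limma, and of 16 others 0 were lower and 5 higher. No test of this split is given because it was drawn from these values. TrpRS-m (-2.80 ± 0.30), AsnRS-m (-2.12 ± 0.20) and CysRS-m (-1.06 ± 0.12) fell with TyrRS-m. The median of all 25 was -0.06, turning positive (0.18) after spike-in centring, and the mean was -0.31, while camera ranked the list upward. In the respiratory chain 9 of 56 genes fell and 1 rose (1 higher and 8 lower adjusted over the list alone), with a median of -0.19 that turned positive (0.05) after spike-in centring. ND-13B of complex I fell by 1.40 ± 0.15 and SdhD of complex II by 0.88 ± 0.16. The nuclear pore list had 4 of 22 lower and 0 higher (8 lower adjusted over the list alone), with Nup37 falling by 2.10 ± 0.34, histone acetylation 4 of 15 with Spt3 falling by 1.66 ± 0.16, and mitosis 6 of 21 with Klp61F falling by 0.80 ± 0.18. Leaving out each array ended the calls of Nup133 in 7 fits, Nup188 in 6 and Nup44A in 1. It also ended those of glu and ncd in the mitosis list in 6, and chm in the histone acetylation list in 3. The spliceosome list had 4 of 33 lower, including Prp38 (-1.37 ± 0.12), with a median of -0.21 turning positive after spike-in centring. Its members U2A and U4-U6-60K lost their calls in 8 and 2 leave-one-out fits. With GST replicate 2 left out, spike-in centring turned 0 negative list medians positive and 14 positive ones negative. None of these lists passed in camera after adjustment. Of all 5906 tested genes 1175 fell and 436 rose in limma. The respiratory chain, nuclear pore and spliceosome lists thus fell no more often than tested genes in general.

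The double-strand break repair kinase gene tefu fell by 1.93 ± 0.23 and Irbp, a Ku subunit gene, rose by 1.72 ± 0.32, in a DNA damage list with 4 of 10 higher and 1 lower in limma (5 and 2 adjusted over the list alone). In the RNA interference list 3 of 11 genes fell, with Hen1, a small RNA methyltransferase gene, at -2.45 ± 0.23, and the median (0.13) and mean (-0.19) differed in sign. The calls of the other members that fell, drosha and loqs, were lost in 6 and 3 of 9 leave-one-out fits. The antimicrobial peptide gene Drs rose by 3.17 ± 0.36, the only called member of 11 immune genes. The hemocyte marker NimC1, the only called member of 20, rose 4.61-fold on the linear scale. On the log2 scale the neuronal gene brp rose by 1.18 ± 0.14 and betaTub60D by 2.25 ± 0.22, the latter close to the rise of NimC1. Of 39 translation factors 2 fell, including eIF4E6 (-3.23 ± 0.22), and 2 rose, eIF6 (1.23 ± 0.28) and eIF2D (0.70 ± 0.22), which lost their calls in 1 and 8 of 9 leave-one-out fits. Of 28 proteasome genes Rpt3R fell (-2.81 ± 0.30) and Rpn1 rose (0.46 ± 0.12), the latter call being lost in 3. The list of insulin, TOR and amino acid stress genes had 3 of 14 higher (4 adjusted over the list alone) with scyl at 0.88 ± 0.20. The unfolded protein response had 2 of 11 higher. Leaving out each array ended the calls of foxo and the glutathione S-transferase gene GstD1 in the first list in 5 and 7 fits. It ended those of Herp and Ero1L in the second list in 2 and 7 fits. Polycomb and trithorax genes had 3 of 18 lower, other MBD and heterochromatin genes 2 of 10, lysosome and autophagy 2 of 25 and mitochondrial import 2 of 17, which were 2, 2, 1 and 0 adjusted over each list alone. Among these, esc and HP1c lost their calls in 8 leave-one-out fits, Atg7 in 7, and Tim9a and PolG1 in 6. E(z) lost its call in 2 and caly in 1, while HP4 and Atg12 kept theirs. The shares that fell in the Polycomb, heterochromatin, lysosome and import lists were near or below that of all tested genes (1175 of 5906). A single gene fell in the nucleolus, lipid, TCA cycle and germline lists and rose in the ecdysone, fat body, homeotic and muscle lists, while the list of snoRNA hosts and polymerase III had 1 of each. Adjusted over the list alone the TCA cycle, germline and ecdysone lists had 0 calls, and leaving out each array ended the calls of ScsbetaG and aub in 8 of 9 fits, bt in 6, dpp in 5, and vri and La in 3. In limma 0 heat shock, apoptosis, JAK/STAT, glia or gut genes were called. With the array set as a block 2 heat shock genes were higher and 5 lower, 4 apoptosis genes higher and 1 lower, and 1 JAK/STAT gene lower. With the replicate number as a block Dcp-1 (0.48 ± 0.16, adjusted p = 0.029) and Hsc70-5 (0.37 ± 0.14, adjusted p = 0.032) passed in limma.

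For the patterns below, the test of the array set and spike-in centring without GST replicate 2 were chosen only after the result was seen, and the others after the pattern was seen but before they were run. Splitting the 9 dsRNA arrays at random into 6 and 3 gave at least as many calls as the real grouping (2098) in 2 of 84 splits, the other being replicate 3 set apart (2206). Within replicate numbers 1 of 27 choices, the real one, did so (3472 against 0). For M1 and for M2 against GST it was 1 of 10 splits each (1239 and 1144 against 0), where 10 splits are too few to tell. For M2 against M1 the real grouping gave 0 calls. Any split gives at least that many, so the 10 of 10 found there decides nothing.

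Falls outnumbered rises (68.9% of calls). Whether the scaling of the arrays could account for this stays open. Spike-in centring left 45.6% falls, but 91.1% with GST replicate 2 left out, and 17.1% to 58.0% with each other array left out, so its result turns on single arrays. Falls still outnumbered rises in replicates 1 and 2 alone (57.5%), so the batch of arrays does not account for all of the excess. The share was lower there than over all arrays, as it was with the array set as a block (58.1%). Since each dsRNA group holds both kinds of array in the same numbers, the block left the fold changes as they were. Their median stayed at -0.03, while 3541 probe sets passed in place of 1843. With the block, the batch may thus bear on the share through which probe sets passed. Without it, an adjusted p under 0.01 gave 76.3% falls. Why the share was lower was not tested.

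Falls were fewer on the X and chromosome 4. None of 10000 draws of genes from chromosomes 2 and 3 matched on expression level held as few falls as the X (136 of 995; drawn mean 215, range 177 to 257), a share given as 1e-04, the smallest step of 10000 draws. Matched on gene length none did either (1e-04; drawn mean 186, range 146 to 221). For chromosome 4 (0 of 42) none of the draws matched on level held 0 falls (1e-04; drawn mean 7.55), and a share of 0.0171 of those matched on length did (drawn mean 3.77). Neither this level nor length alone is therefore likely to account for the pattern, though the draws matched them singly. Level here was the mean over all arrays, which a fall itself lowers. The draws therefore do not decide on the level in GST arrays, which was not matched.

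Genes that fell were short, with a median length of 1531 bp (1171 genes) against 3304 bp for genes that rose (436) and 3394 bp for those not called (4284). Draws of genes that did not fall, matched on the mean level over all arrays, had a mean median of 3358 bp. None of 10000 was as short (given as 1e-04). The level in GST arrays was not matched here either. Without the mitochondrial ribosomal protein genes the median was 1587 bp, and again no draw was as short (1e-04). Genes that fell may also lie next to each other, with 228 of 5001 adjacent pairs both lower against 202 (152 to 243) when permuted (p = 0.0177, one-sided permutation), and 126 of 2446 pairs under 1 kb apart against 98.9 (p = 0.0025). With the array set as a block these were, by the same one-sided permutation, 527 against 498 (p = 0.0417) and 307 against 244 (p = 1e-04). The permutation did not hold gene length fixed, which could produce part of this excess.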
